A study of Mus musculus with 8 samples.

How the data were processed

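CD4+ T cells of C57BL/6 mice were profiled in 4 groups of 2 samples: tumour-free or bearing the fibrosarcoma MCA205-OVA, each with a control antibody or an antibody against the IL-6 receptor. Per the labels' protocols, the mice received OVA-specific transgenic CD4+ T cells and peptide-loaded dendritic cells, CD4+ T cells were isolated 4 days after immunisation, and cyanine-3 cRNA was made from 0.1 µg of RNA. The purity of the isolates, the antibodies and doses, the number of mice per sample and which samples belong to the same experiment are not given in the sources used here.

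The deposited scanner files hold 1 array per sample with 62976 spots, of which 3671 were controls. Their signals are intensity values, which the authors obtained with Agilent Feature Extraction 10.10.1.1, per the submitters' processing notes. Per the file headers, the spot signal was background-subtracted and detrended, with a surrogate value for spots not above background and no dye normalization. The deposited value table holds log2 values, and its processing is not given in the sources used here. Each of its columns equalled the log2 of the processed signal of the same array minus the array's 75th percentile (r = 1, spread of the offset at most 0.00134). No sample was left out and no value fell outside its stated unit.

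Values were recomputed from the scanner files. Spots that the scanner software marked as outliers were dropped (60 to 95 per array), spots of the same probe were averaged, and 18 probes without a usable spot on some array were left out, which left 56587. The signals were taken as log2 minus the array's 75th percentile, which lay between 500 and 526 before scaling. A probe was kept if the software called it well above background on both arrays of at least 1 group (32039 probes). Each gene was represented by its kept probe with the highest mean over all arrays, which gave 21519 genes. Of these, 6922 had more than 1 kept probe. Names followed the reference table by accession for 32989 probes and by symbol or synonym for 10747, while 12869 kept the name in the file; 2053 symbols changed. The file's probe positions were on the same chromosome as the reference gene for 99.6% of 43631 probes and inside its span for 9.76%, so they belong to a build that the files do not name.

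On each array 53.1% to 59.8% of probes lay well above background. The lowest signal so called was 24.2 to 36.3, which sets the smallest level that can be told from 0. Where no probe of a gene was well above background on any array of a group, a change is given as a bound, "at least N-fold". For it, signals of the dim group below the lowest well-above-background signal of their array were raised to that signal, and the difference of the group means was taken. Where a gene's own probe was dim on both arrays of a group but another of its probes was not, and in the difference between the antibody effects in the 2 hosts, no bound was computed and the size is not exact.

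Differences between groups were tested in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table). All 8 arrays were fitted as 4 group means (4 residual degrees of freedom, prior degrees of freedom 4.16), with an intensity trend in the variance. Tests were two-sided and p-values were adjusted over the 21519 genes of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Host and antibody averages came from an additive model of both factors (5 residual degrees of freedom). The difference between the antibody effects in the 2 hosts was the interaction term of the 4-group fit. Gene lists (40, each with at least 5 measured genes) were tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the data and with fry, adjusted over the lists. Counts within a list are also given adjusted over the list alone. A list's median is over its measured genes. Correlations between comparisons were set beside 200 simulated sets of unchanged groups with the residual spread, genes being independent, and 200 in which genes moved together along the 4 residual patterns of the fit. The central 95% of each is given. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

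The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were, per comparison, up to 10 per direction with the largest change past the threshold, at least 2-fold, with an official-style symbol and arrays that did not overlap between groups. Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were named. The rule added 26 genes chosen in advance, of which 1 is not reported here, and up to 4 measured members with the smallest p of each list described. Immunoglobulin features were listed from the file's descriptions after the data were examined, because many of them changed. Their variable segments share sequence, so a probe may read several of them.

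The tests were run on simulated data made from the real arrays' means and spread, in 10 runs with 200 of 21519 genes changed. Filtering, probe choice and scaling were not simulated, and genes varied independently of each other. For the comparison of hosts under control antibody, 75.7% of 2-fold and 94.4% of 4-fold changes were recovered, with 6.59% of calls false. For the host average these were 88.2%, 98.6% and 5.56%. With nothing changed, the comparison of antibodies in tumour-free mice gave 1 call in 10 runs. A shift of 0.5 in the Tfh list was called in 10 of 10 runs, and 0 calls fell on the 32 other lists tested beside it. Since genes were independent in these runs, the rates need not hold for real lists whose genes move together.

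The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the deposited value table, no filter, a filter on all 8 arrays, the mean of a gene's probes, no trend, a robust prior, array weights, a fit of only the 4 arrays compared, an adjusted p under 0.10, a 2-fold minimum, the 2 other list tests, and leaving out each array in turn. A setting without immunoglobulin features and without markers of other cell types was added after the data were examined.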

Results

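Gene expression in CD4+ T cells was measured on 8 one-colour microarrays, each with 62976 spots for the mouse transcriptome. The cells came from C57BL/6 mice that were tumour-free or carried MCA205-OVA, a fibrosarcoma made to express ovalbumin (OVA). The mice had received CD4+ T cells with a transgenic receptor for OVA, then dendritic cells loaded with the OVA peptide, together with a control antibody or an antibody against the IL-6 receptor (anti-IL-6R). CD4+ T cells were isolated on day 4. The 4 groups held 2 arrays each: tumour-free with control antibody (replicates 1 and 2), tumour-bearing with control antibody (replicates 3 and 4), tumour-free with anti-IL-6R (replicates 5 and 6) and tumour-bearing with anti-IL-6R (replicates 7 and 8). The series is about an IL-6-dependent loss of Th1 responses, those of interferon-gamma-producing helper T cells, in mice with tumours. Its design sets tumour-bearing against tumour-free mice and, in tumour-bearing mice, anti-IL-6R against control antibody. The 2 by 2 layout also gives the antibody effect in tumour-free mice, the tumour effect under anti-IL-6R, and the test of whether the antibody effect differed between hosts.

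Between 53.1% and 59.8% of probes lay well above background on an array, and no spot was saturated. The correlation of log2 signals across tested genes was 0.993 to 0.994 within groups and 0.978 to 0.992 between arrays of different groups. The first principal component held 38.8% of the variance and set replicates 3 and 4, at 53.9 and 40.7, apart from the other 6 arrays, which lay between -28.5 and -1.81. All 8 arrays shared 1 slide and 1 scan. The control antibody arrays filled 1 slide column and the anti-IL-6R arrays the other, with tumour-free mice in rows 1 and 2 and tumour-bearing mice in rows 3 and 4. Slide position therefore cannot be told apart from host and antibody, neither in comparisons of single groups nor in the host and antibody averages. The labels give 2 independent experiments per condition but not which arrays belong to the same experiment, so p-values measure the spread between these samples. Changes are log2 differences of scaled signals ± their standard error (SE) with n = 2 arrays per group, tested in limma. Only 2 arrays per group limit the precision of every value.

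Under control antibody, CD4+ T cell isolates of tumour-bearing mice had more transcript of Maf, the transcription factor c-Maf, than those of tumour-free mice, by 1.13 ± 0.09 (adjusted p = 0.0013). Markers of other cell types also moved in this comparison, as given below, so which cells carried the changes cannot be told. Il21 and Il4, cytokine genes of helper T cells that c-Maf activates, rose by 3.18 ± 0.30 and 2.5 ± 0.17 (adjusted p = 0.0017 and 0.0007). Pdcd1, the gene of the inhibitory receptor PD-1, rose by 1.81 ± 0.12, and Gzmb, which encodes the cytotoxic protease granzyme B, by 1.75 ± 0.24 (adjusted p = 0.0007 and 0.0073). Ctla4 rose by 0.90 ± 0.17, Bcl6, the lineage factor of follicular helper T cells, by 0.54 ± 0.09, Foxp3, that of regulatory T cells, by 0.40 ± 0.09, and Gata3, that of Th2 cells, by 0.39 ± 0.09 (adjusted p = 0.025, 0.017, 0.036 and 0.039). A second probe of Bcl6 gave -0.04 and a second probe of Il21 0.58. Ifng, the Th1 cytokine gene, stood at -0.69 ± 0.25 (adjusted p = 0.14), and Tbx21, which encodes the Th1 factor T-bet, at 0.46 ± 0.13 (adjusted p = 0.07), neither past the threshold. Other genes chosen in advance that did not pass were Il10 (1.04, adjusted p = 0.17), Stat3 (0.26, adjusted p = 0.086), Socs3 (0.48), Eomes (0.42), Il12rb2 (0.33), Prdm1 (0.28), Stat4 (0.10), Il2 (0.44), Il6st (0.05), Il6ra (-0.26), Tnf (-0.28) and Cd40lg (-0.34). Il6 and Il17a were not measured, being well above background on 1 and 0 arrays. Maf, Il21, Il4, Pdcd1 and Gzmb kept their calls when each of the 8 arrays was left out in turn. The other calls depended on single arrays: Ctla4 lost its call without replicate 1, 2 or 4, Bcl6 without 2, 3 or 4, Foxp3 without 1, 2, 3, 4, 5 or 6, and Gata3 without 1, 2, 3, 5, 7 or 8.

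**Figure D1:**
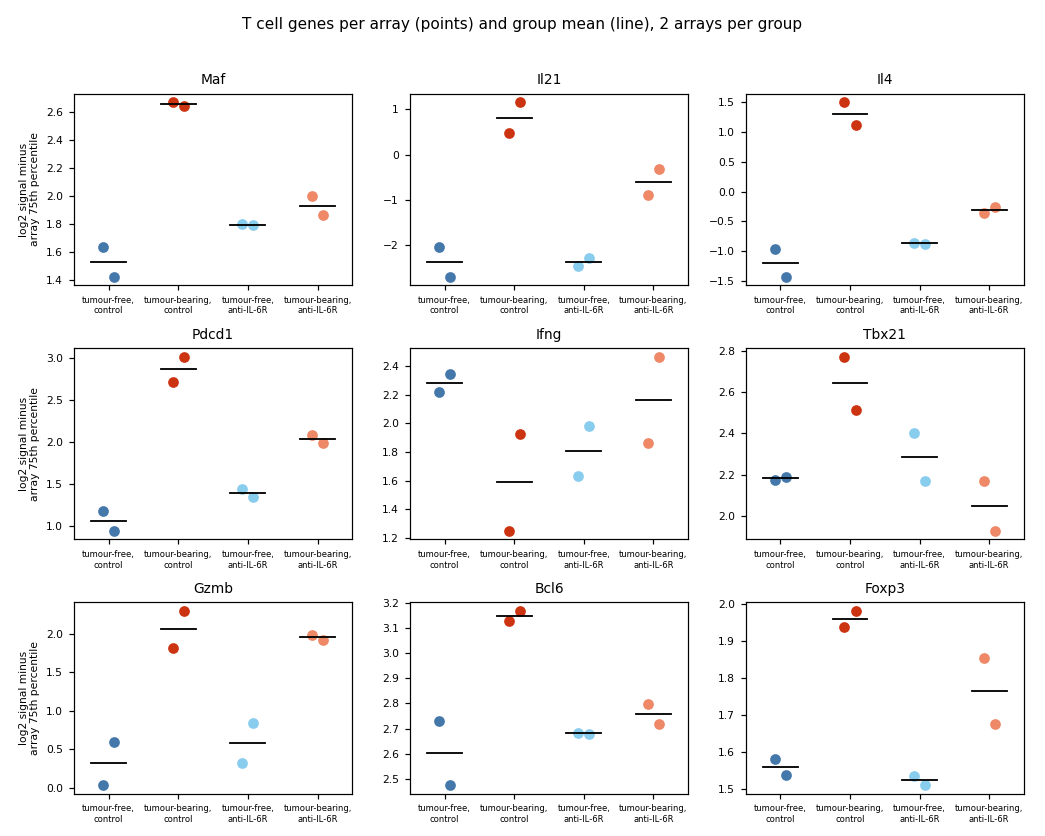
Signals of 9 T cell genes on each array (points) and their group mean (line), as log2 signal minus the array's 75th percentile, with 2 arrays per group. Maf, Il21, Il4 and Pdcd1 lay higher on both control antibody arrays of tumour-bearing mice than on the other 6 arrays, while Ifng passed the threshold in no comparison.

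At an adjusted p under 0.05, 1342 of 21519 genes changed between tumour-bearing and tumour-free mice under control antibody, 917 higher and 425 lower, and 517 of them changed by at least 2-fold. Immunoglobulin features made up 127 of the 917. Among the largest rises of other genes were transcripts of neutrophil granules: Ltf (lactoferrin) at 4.95 ± 0.34, Camp (cathelicidin) at 4.31 ± 0.23 and Ngp (neutrophilic granule protein) at 4.28 ± 0.32 (adjusted p = 0.0007, 0.00034 and 0.00082). Red cell genes rose too, with Rhd, which encodes a blood group antigen, at 4.66 ± 0.54 and Ahsp, the stabilising protein of alpha-haemoglobin, at 4.59 ± 0.56 (adjusted p = 0.0045 and 0.0052). Slc38a5, an amino acid transporter gene, rose by 4.63 ± 0.60 and Apol11b by 4.46 ± 0.34. Ltf, Ngp, Slc38a5 and Apol11b were dim on 1 of the 2 tumour-free arrays, so the sizes of their rises are not exact. For genes not well above background on either array of a group, only a bound was available: Cldn13 was at least 8.76-fold higher, Sox6 at least 5.54-fold and Tom1l1 at least 4.83-fold (adjusted p = 0.006, 0.0099 and 0.0043). Hspa1a and Hspa1b, the stress-inducible heat shock protein 70 genes, fell by 2.8 ± 0.42 and 2.74 ± 0.39, and Atf3, a stress-induced transcription factor, fell by 2.43 ± 0.41 (adjusted p = 0.01, 0.0086 and 0.016). Only the tumour-free control antibody group stood apart for Hspa1a and Hspa1b, with means of 4.47 and 3.85. Their means were 1.69 and 1.11 in tumour-bearing mice under control antibody. Under anti-IL-6R they were 1.87 and 1.40 in tumour-free and 1.74 and 1.02 in tumour-bearing mice. Pramel6 fell by 2.13 ± 0.31, a size that is not exact, since it was dim on 1 of the 2 tumour-bearing arrays. The long non-coding RNA Firre fell by 3.63 ± 0.29, though another Firre probe gave -0.13. Its mean was 0.34 in tumour-free and -3.29 in tumour-bearing mice under control antibody, and -3.45 and -3.18 under anti-IL-6R. Krt5, Col19a1, Sntg2, Chsy3 and Kcnv1 were at least 6.44-fold, 3.75-fold, 3.21-fold, 2.46-fold and 2.43-fold lower, each dim on both arrays of tumour-bearing mice (adjusted p = 0.032, 0.004, 0.042, 0.023 and 0.014). Col19a1, Sntg2 and Kcnv1 were also dim on all anti-IL-6R arrays. Krt5 differed between the 2 tumour-free arrays (SD 2.18) and lost its call without replicate 1, 3 or 4. Sntg2 lost it without 1, 2, 4 or 7, and Chsy3 and Kcnv1 without 1, 2 or 3. Atf3 lost its call without replicate 1, 2 or 4, Sox6 without 2 or 3, and Hspa1a, Hspa1b and Pramel6 without 2. Without replicate 1, 2, 3 or 4 the count was 893, 287, 543 and 842 genes, and it was 569 with no filter on dim probes, 621 without a trend in the variance and 764 with array weights. Of the 111 named genes past the threshold, 45 kept their call with each array left out in turn, and 64 lost it without replicate 2.

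Of 40 gene lists fixed in advance, 25 moved in this comparison by camera's test, 17 up and 8 down. None held with an estimated correlation between genes (smallest adjusted p = 0.19), while fry, which tests whether a list's genes move 1 way without comparing them with other genes, called 15. In the follicular helper (Tfh) list, all 18 measured genes had a change above 0, with a median of 0.86, and 14 rose (18 when adjusted over the list alone). These included Ascl2, a Tfh transcription factor, at 2.92 ± 0.18, the costimulatory receptor gene Icos at 1.16 ± 0.08, and Tox2 at 1.53 ± 0.11. Tox2 was read from its brightest probe, and another probe gave a far smaller difference between antibody effects, as stated below. In the regulatory T cell list 14 of 20 rose (18 adjusted over the list alone), among them Tnfrsf4 (OX40) at 1.19 ± 0.07, Tnfrsf9 (4-1BB) at 1.13 ± 0.09 and Tnfrsf18 (GITR) at 0.63 ± 0.07. These 3 receptors also stand for T cell activation. The list of c-Maf and its reported targets had 7 of 15 genes up (8 adjusted over the list alone), including the inhibitory receptor gene Tigit at 1.86 ± 0.17. Lag3 rose by 1.81 ± 0.17. Th2 genes rose in 7 of 13 (9 adjusted over the list alone), with Il1rl1, the IL-33 receptor, at 1.42 ± 0.13 and Ccr4 at 1.08 ± 0.18. Th17 genes rose in 5 of 12 (6 adjusted over the list alone), with Rora at 0.79 ± 0.07, Ahr at 0.99 ± 0.18 and Il1r1 at least 4.76-fold higher. Camera's adjusted p was 1.1e-17 for Tfh, 2.3e-12 for regulatory, 4.5e-08 for c-Maf, 4.1e-05 for Th2 and 0.00029 for Th17 genes, against an adjusted p = 0.19 with an estimated correlation for each. The lists overlap: 14 of the 15 genes in the c-Maf list and 9 of the 18 in the Tfh list are also in another. Ahr lost its call without replicate 1, 2 or 3, as did Ccr4, and Il1r1 lost it without 1, 2 or 4.

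The Th1 list had a median of 0.18, with 6 of 24 genes up (7 adjusted over the list alone, with 1 lower). Its difference from the other lists was not tested. Il12rb1, a chain of the IL-12 receptor, rose by 0.80 ± 0.10, the chemokine receptor gene Cxcr6 by 0.88 ± 0.12, Nkg7 by 0.62 ± 0.11 and Ly6c2 by 0.50 ± 0.08 (camera's adjusted p = 0.041). This list's adjusted p = 0.31 with an estimated correlation, and it lost its call without replicate 1 or 3 (adjusted p up to 0.14). Cxcr6 lost its call without replicate 2, Nkg7 without 1, 2 or 3 and Ly6c2 without 2 or 3. Genes of the cell cycle all had a change above 0, with a median of 0.53 over 54 genes, of which 20 rose (50 adjusted over the list alone). The proliferation marker Mki67 was up by 0.77 ± 0.15 and the S-phase regulators E2f1 and Ccne1 by 0.63 ± 0.10 and 0.63 ± 0.11 (camera's adjusted p = 3.4e-19, adjusted p = 0.36 with an estimated correlation). Mki67 and Ccne1 lost their calls without replicate 1, 2 or 3 and E2f1 without 2 or 3. Chemokine receptor and homing genes rose in 10 of 22 (13 adjusted over the list alone), including Ccr2 at 1.46 ± 0.15 and Itgb1 at 0.86 ± 0.13 (camera's adjusted p = 5.8e-05, adjusted p = 0.19 with an estimated correlation). The list of T cell activation genes had 8 of 24 up (camera's adjusted p = 0.033, adjusted p = 0.39 with an estimated correlation) and that of inhibitory receptors 5 of 18, with Cd200 at 0.69 ± 0.08 (0.0063, adjusted p = 0.19 with an estimated correlation). Itgb1 lost its call without replicate 2, and the activation list without 1, 4, 7 or 8. In the same arrays the erythroid and neutrophil marker lists shifted by medians of 1.60 and 1.55, B cell markers by -0.70 and pan T cell markers by 0.15.

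The list of AP-1 and other immediate early genes had a median of -0.37, with 6 of 21 lower and 2 higher (14 and 2 adjusted over the list alone). Jun fell by 0.90 ± 0.11 and Klf4 by 1.32 ± 0.18, while Egr2 rose by 0.73 ± 0.11 (camera's adjusted p = 1.2e-06, adjusted p = 0.40 with an estimated correlation). Heat shock genes fell in 3 of 16 (7 adjusted over the list alone), with Dnajb4 at -0.84 ± 0.12 beside Hspa1a and Hspa1b (camera's adjusted p = 5.6e-05, adjusted p = 0.38 with an estimated correlation). Interferon response genes had a median of 0.25. Isg20 (0.90 ± 0.13), Zbp1 (0.69 ± 0.11), Isg15 (1.02 ± 0.20) and Rsad2 (2.13 ± 0.43) were the 4 of 46 that rose (10 adjusted over the list alone; camera's adjusted p = 5.8e-05, adjusted p = 0.49 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.19 with 1 of 41 up, Ndufb9 at 0.41 ± 0.09 (camera's adjusted p = 5e-07, adjusted p = 0.51 with an estimated correlation). Glycolysis genes rose in 4 of 20 and fell in 1, with Tpi1 at 0.65 ± 0.07 and Pfkl at -0.68 ± 0.10 (camera's adjusted p = 0.0093, adjusted p = 0.43 with an estimated correlation). The naive and quiescence list had a median of -0.15 (camera's adjusted p = 0.0015, adjusted p = 0.51 with an estimated correlation), the NF-kappaB list -0.06 (0.038, adjusted p = 0.44 with an estimated correlation), and the ribosome list -0.05 (0.011, adjusted p = 0.81 with an estimated correlation). The ribosome median lay above 0 under quantile normalization. Egr2, Klf4, Dnajb4, Isg20 and Pfkl lost their calls without replicate 2, Zbp1 without 2 or 4, Isg15 and Rsad2 without 1, 2 or 3, and Ndufb9 without 2, 3, 4, 5 or 6. The heat shock list lost its call without replicate 1, the naive list without 3, and the NF-kappaB and ribosome lists without 1 or 3. These arrays also carried the erythroid and neutrophil shifts of 1.60 and 1.55. Lists not past the threshold were those of the IL-6 receptor and STAT3 response (median 0.25, camera's adjusted p = 0.069), cytotoxic effectors (0.15, 0.25), TGF-beta signalling (-0.07, 0.12), the unfolded protein response (0.02, 0.74), hypoxia (-0.03, 0.78), cholesterol synthesis (0.12, 0.20), apoptosis (0.01, 0.60) and p53 targets (0.05, 0.85).

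Markers of other cell types moved in opposite directions in this comparison. Erythroid genes had a median of 1.60 (1.36 with the 2 genes that had only a bound set to it), and 13 of 22 rose (20 adjusted over the list alone). They included the erythroid factor Gata1 at 0.79 ± 0.09, the red cell anion exchanger Slc4a1 at 3.99 ± 0.51 and Car2, carbonic anhydrase 2, at 2.87 ± 0.38 (camera's adjusted p = 8.1e-12, adjusted p = 0.32 with an estimated correlation). Neutrophil and myeloid suppressor genes had a median of 1.55 and rose in 8 of 23 (14 adjusted over the list alone, with 1 lower). Mpo, myeloperoxidase, stood at 3.12 ± 0.20 beside Camp, Ltf and Ngp (camera's adjusted p = 4.5e-08, adjusted p = 0.32 with an estimated correlation). Plasma cell genes rose in 5 of 9 (6 adjusted over the list alone). Derl3 stood at 1.60 ± 0.13, Mzb1 at 1.22 ± 0.15 and the immunoglobulin joining chain gene Jchain at 1.76 ± 0.29 (camera's adjusted p = 8.1e-06, adjusted p = 0.23 with an estimated correlation). Among 181 immunoglobulin features, a list made after the values were seen, 127 rose and 1 fell, and between 62 and 133 rose with 1 array left out. The plasma cell median was 1.22, or 0.68 with the 2 members that had only a bound set to it. B cell genes had a median of -0.70 and 7 of 18 fell (10 adjusted over the list alone). Among them were Cr2 at -1.09 ± 0.18, Bank1 at -0.95 ± 0.18 and Ebf1 at -1.32 ± 0.26 (camera's adjusted p = 2.3e-09, adjusted p = 0.36 with an estimated correlation). Natural killer cell genes had a median of -0.37 with 5 of 16 lower and 2 higher (7 and 3 adjusted over the list alone). Those lower included Gzma at -0.85 ± 0.10 and the receptor gene Klra8 at -1.17 ± 0.13 (camera's adjusted p = 0.00077, adjusted p = 0.32 with an estimated correlation). Endothelial genes had a median of -0.31 (camera's adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation) and pan T cell genes 0.15 (0.034, adjusted p = 0.70 with an estimated correlation). Not past the threshold were markers of macrophages (-0.18, 0.54), dendritic cells (-0.21, 0.48), CD8 T cells (0.12, 0.78), gamma-delta and NKT cells (-0.13, 0.57), megakaryocytes (-0.27, 0.073), basophils and mast cells (-0.09, 0.82) and stroma (0.17, 0.35). Single basophil and monocyte genes rose, Prss34 at least 2.72-fold (adjusted p = 0.0099) and Chil3 by 2.38 ± 0.28 (adjusted p = 0.0047). Without replicate 3 the erythroid median was 1.06 and the natural killer one -0.65. The natural killer list lost its call without replicate 4, the endothelial list without 1 or 4, and the pan T cell list without 2 or 4. Jchain lost its call without replicate 1, 2 or 3, Cr2 and Bank1 without 2 or 4, and Ebf1 and Prss34 without 2, 3 or 4.

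**Figure D2:**
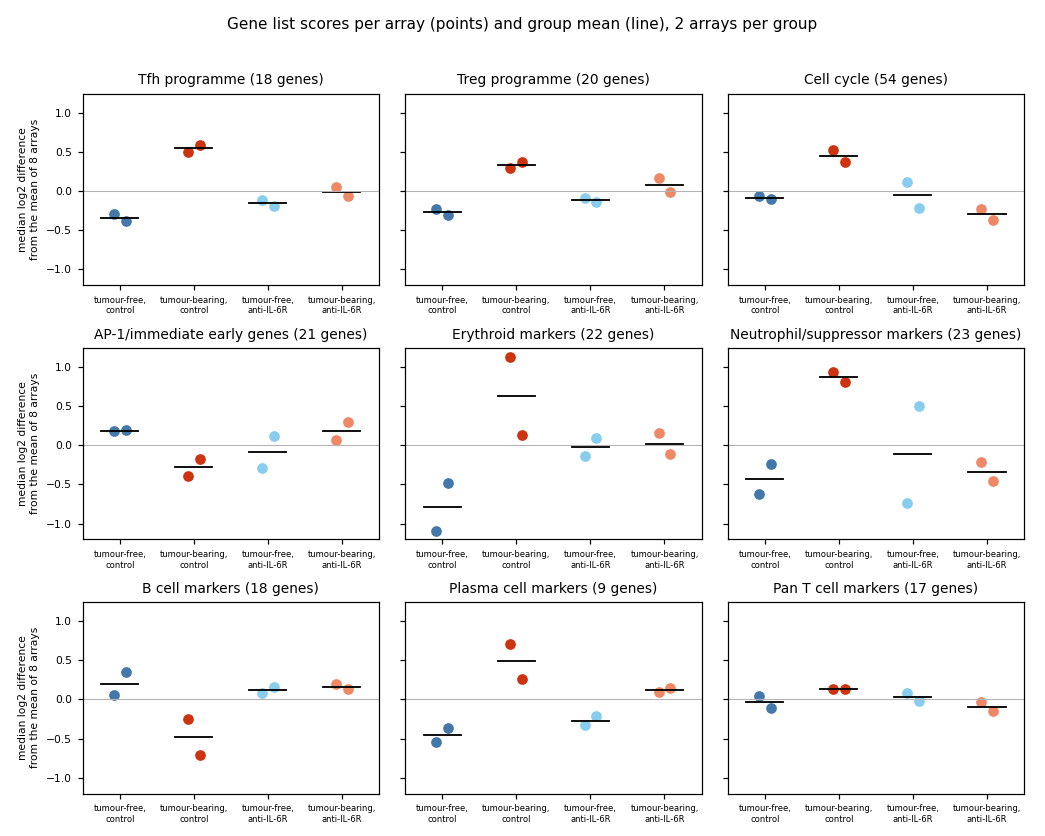
Scores of 9 gene lists on each array (points) and their group mean (line), each score being the median over the list's genes of the log2 difference from the mean of 8 arrays. Tfh scores were 0.50 and 0.59 on the control antibody arrays of tumour-bearing mice and lay between -0.38 and 0.05 on the others, while erythroid scores of those arrays were 1.13 and 0.13.

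In tumour-bearing mice, anti-IL-6R lowered transcripts of several of the genes that were higher there under control antibody. Maf fell by 0.72 ± 0.09, Il4 by 1.61 ± 0.17, Pdcd1 by 0.83 ± 0.12 and Il21 by 1.43 ± 0.30 (adjusted p = 0.024, 0.02, 0.024 and 0.039). Group means of Maf, in log2 signal relative to the array's 75th percentile ± SD (n = 2 arrays), were 1.53 ± 0.15 in tumour-free and 2.66 ± 0.02 in tumour-bearing mice under control antibody, and 1.80 ± 0.01 and 1.93 ± 0.10 under anti-IL-6R. Tbx21 fell by 0.60 ± 0.13, Gata3 by 0.47 ± 0.09, and Stat3, the transcription factor downstream of the IL-6 receptor, by 0.34 ± 0.08 (adjusted p = 0.04, 0.028 and 0.044). Other probes of Il21 and Stat3 gave 0.04 and 0.03. Ifng stood at 0.58 ± 0.25 (adjusted p = 0.17), Socs3, a feedback inhibitor that STAT3 induces, at -0.87 ± 0.23 (adjusted p = 0.059), Bcl6 at -0.39 ± 0.09 (adjusted p = 0.051) and Il6st, the shared receptor chain gp130, at -0.33 ± 0.09 (adjusted p = 0.063), none past the threshold. Nor did Il6ra (0.25), Foxp3 (-0.20), Ctla4 (0.04), Gzmb (-0.10), Il10 (0.50), Eomes (-0.31), Il2 (-0.58), Tnf (0.02), Stat4 (-0.23), Il12rb2 (-0.11), Prdm1 (0.10) or Cd40lg (0.23). Without replicate 8 none of these 7 calls held (adjusted p = 0.12 for Maf, 0.075 for Il4, 0.145 for Pdcd1, 0.145 for Il21, 0.24 for Tbx21, 0.17 for Gata3 and 0.24 for Stat3). Maf and Gata3 also lost their calls without replicate 3, Pdcd1 without 4, Il21 without 3, 4 or 7, Tbx21 without 1, 2, 3 or 4, and Stat3 without 1, 2, 3, 4 or 7.

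Anti-IL-6R changed 1261 of 21519 genes in tumour-bearing mice, 439 higher and 822 lower. Among the 321 that changed at least 2-fold the direction turned, with 208 higher and 113 lower. Neutrophil granule genes were among the largest falls: Camp fell by 4.52 ± 0.23, Ltf by 4.91 ± 0.34 and Mpo, myeloperoxidase, by 3.21 ± 0.20, while Ngp was at least 21.3-fold lower (adjusted p = 0.00094, 0.0023, 0.0014 and 0.0014). Rhd, the blood group gene, and Cldn13 fell by 2.87 ± 0.54 and 2.80 ± 0.60 (adjusted p = 0.03 and 0.04). Sox6 was at least 5.84-fold lower, the glucose transporter gene Slc2a4 at least 3.55-fold, Apol10a at least 2.68-fold and Pdia2 at least 1.64-fold (adjusted p = 0.035, 0.037, 0.024 and 0.03). Among rises, Ccn2, a matricellular growth factor gene, gained 2.76 ± 0.27 and Atf3 2.47 ± 0.41 (adjusted p = 0.016 and 0.026). Osmr, a receptor gene of the IL-6 cytokine family, was at least 1.87-fold higher (adjusted p = 0.026). The olfactory receptor genes Olfr943, Olfr743 and Olfr1065 were at least 4.38-fold, 2.87-fold and 1.91-fold higher, and Prickle4, Txndc8, Iqca1l and Lingo2 at least 4.83-fold, 3.58-fold, 2.32-fold and 2.04-fold, all 7 dim on both control antibody arrays. Each of these 7 lost its call without replicate 3, 4 or 8, and Olfr943 differed between the 2 anti-IL-6R arrays (SD 1.62). The count was 19 without replicate 8, with 8 of the 1261 genes among them, and 215, 263, 823 and 840 without replicate 3, 4, 1 and 2. More genes were higher than lower without replicate 3 (158 and 57) and without replicate 8 (13 and 6). Without a filter on dim probes 25 genes passed, 12 of them higher, without a trend in the variance 87, 41 of them higher, and in a fit of the 4 arrays alone 697. Of the 102 named genes past the threshold, Camp, Ltf, Mpo, Ngp and Tox2 kept their call with each array left out in turn, and the others lost it without replicate 8. For Tox2 this holds for its brightest probe, and another probe did not show the difference between antibody effects given below.

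Of the 40 lists, 26 moved in this comparison, 12 up and 14 down, 0 with an estimated correlation (smallest adjusted p = 0.38) and 13 by fry. Cell cycle genes moved together: all 54 had a change below 0, with a median of -0.76, and 43 fell (50 adjusted over the list alone). Ccne1 fell by 0.85 ± 0.11, E2f1 by 0.71 ± 0.10, and the mitotic genes Nuf2 and Ccnb2 by 0.87 ± 0.13 and 0.90 ± 0.14 (camera's adjusted p = 1.5e-24, adjusted p = 0.38 with an estimated correlation). In the Tfh list 9 of 18 fell (14 adjusted over the list alone), with Tox2 at -1.50 ± 0.11 and Cxcr5, the homing receptor of follicular T cells, at -1.21 ± 0.16 (camera's adjusted p = 5.8e-09, adjusted p = 0.38 with an estimated correlation). Genes of the c-Maf list fell in 6 of 15 and rose in 1 (8 and 1 adjusted over the list alone), with Tigit at -0.93 ± 0.17 (camera's adjusted p = 0.0042). Th2 genes fell in 4 of 13 (6 adjusted over the list alone), with Ccr4 at -1.12 ± 0.18 and Il1rl1 at -0.84 ± 0.13 (0.03). Th17 genes fell in 4 of 12 (8 adjusted over the list alone), with Rora at -0.68 ± 0.07 and Batf at -0.51 ± 0.09 (0.0014). Regulatory T cell genes fell in 4 of 20 (6 adjusted over the list alone), with Tnfrsf4 at -0.50 ± 0.07 and Izumo1r at -0.67 ± 0.11 (0.0045). Chemokine receptor genes fell in 7 of 22 with 1 higher (12 and 2 adjusted over the list alone), with Ccr2 at -0.96 ± 0.15 (0.0051). For each of these 5 lists the adjusted p = 0.38 with an estimated correlation. The list of the IL-6 receptor and STAT3 response had a median of -0.15 (camera's adjusted p = 0.20) and the Th1 list of -0.08 (0.26), neither past the threshold. In the Th1 list Il12rb1 fell by 0.81 ± 0.10, Cxcr6 by 0.96 ± 0.12 and Cxcr3 by 0.63 ± 0.11, while Klrd1 rose by 0.52 ± 0.10. Without replicate 8 each gene named here except Tox2 lost its call (adjusted p between 0.08 for Rora and 0.20 for Klrd1), and the Th2 list lost its call without replicate 7 (adjusted p = 0.15). Neutrophil and erythroid markers moved by medians of -1.55 and -0.54 on the same arrays, and pan T cell markers by -0.24.

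Immediate early genes had a median of 0.52, and 9 of 21 rose (15 adjusted over the list alone, with 2 lower). Risers included Jun at 0.68 ± 0.11, Klf4 at 1.13 ± 0.18 and the phosphatase gene Dusp2 at 0.52 ± 0.09 (camera's adjusted p = 5.3e-08, adjusted p = 0.38 with an estimated correlation). The pro-apoptotic genes Bbc3 and Pmaip1 rose by 1.24 ± 0.13 and 0.92 ± 0.14, while the apoptosis list had a median of 0.00 (camera's adjusted p = 0.58). The chemokine gene Ccl3 rose by 1.47 ± 0.17, in an NF-kappaB list with a median of 0.02 (camera's adjusted p = 0.037, adjusted p = 0.44 with an estimated correlation) that median scaling turned to -0.01. Il7r, the IL-7 receptor of resting T cells, rose by 0.69 ± 0.09, and the amino acid synthesis gene Asns fell by 1.25 ± 0.14. Genes of oxidative phosphorylation fell in 3 of 41 (27 adjusted over the list alone), with a median of -0.26 (camera's adjusted p = 7.7e-10, adjusted p = 0.47 with an estimated correlation). Those of cholesterol synthesis fell in 2 of 21 (14 adjusted over the list alone), with a median of -0.36 (1.4e-05, adjusted p = 0.44 with an estimated correlation). In glycolysis, 3 of 20 fell, among them Gapdh at -0.35 ± 0.08, and Pfkl rose by 0.53 ± 0.10 (camera's adjusted p = 0.0042, adjusted p = 0.43 with an estimated correlation). Bbc3, Pmaip1, Ccl3, Il7r, Asns, Jun, Klf4, Dusp2, Gapdh and Pfkl all lost their calls without replicate 8 (adjusted p between 0.054 for Bbc3 and 0.26 for Gapdh), and the NF-kappaB list lost its call without replicate 1, 2, 3 or 8. Neutrophil markers had fallen by a median of 1.55 on these arrays.

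Other cell types' markers moved with the antibody in tumour-bearing mice. Neutrophil genes had a median of -1.55 and 8 of 23 fell (14 adjusted over the list alone, with 1 higher; camera's adjusted p = 3.5e-06, adjusted p = 0.38 with an estimated correlation). Erythroid genes had a median of -0.54 with 6 of 22 lower (10 adjusted over the list alone, with 1 higher), among them Gata1 at -0.85 ± 0.09 and Klf1 at -0.99 ± 0.19 (camera's adjusted p = 0.0006, adjusted p = 0.52 with an estimated correlation). Endothelial genes had a median of 0.92 and 5 of 10 rose (8 adjusted over the list alone). These were led by Robo4 at 1.69 ± 0.17, Cldn5 at 1.22 ± 0.23 and Egfl7 at 1.16 ± 0.21 (camera's adjusted p = 1.2e-06, adjusted p = 0.38 with an estimated correlation). B cell genes had a median of 0.63 with 5 of 18 higher (12 adjusted over the list alone), including Cr2 at 0.92 ± 0.18 (camera's adjusted p = 6.4e-09, adjusted p = 0.38 with an estimated correlation). Natural killer cell genes had a median of 0.54 with 6 of 16 higher (7 adjusted over the list alone, with 2 lower), including Klra8 at 1.17 ± 0.13 (camera's adjusted p = 1.8e-05, adjusted p = 0.38 with an estimated correlation). The macrophage list had a median of 0.46, with Cd14 at 1.14 ± 0.25. The megakaryocyte list had 0.36, with Ppbp at 1.04 ± 0.18, and the plasma cell list -0.43, with Derl3 at -0.92 ± 0.13 (camera's adjusted p = 0.00013, 0.0087 and 0.031, against an adjusted p = 0.44, 0.38 and 0.44 with an estimated correlation). Medians moved with single arrays: the erythroid one was -0.15 without replicate 3 and -0.90 without 4, the B cell one 0.37 without 4, the macrophage one 0.71 without 3 and 0.16 without 4, and the megakaryocyte one 0.75 without 8 and 0.15 without 7. The erythroid list lost its call without replicate 3, the macrophage list without 4, the megakaryocyte list without 7 and the plasma cell list without 3 or 7. The endothelial, B cell, natural killer and neutrophil lists kept theirs with each array left out, although each gene named in this paragraph lost its own call without replicate 8 (adjusted p between 0.075 for Gata1, Robo4 and Klra8 and 0.18 for Klf1 and Cd14).

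In tumour-free mice, 4 genes differed between anti-IL-6R and control antibody, 2 higher and 2 lower, and 1705 had an unadjusted p under 0.05. The olfactory receptor gene Olfr913 was at least 6.44-fold higher, and Firre fell by 3.79 ± 0.29, with -0.15 at another Firre probe (both adjusted p = 0.0075). The other 2 are 4930523O13Rik, higher, and C530050E15Rik, lower, named after their values were seen. Maf stood at 0.27 ± 0.09 (adjusted p = 0.59), Il21 at -0.01, Il4 at 0.33, Pdcd1 at 0.33, Ifng at -0.48 and Tbx21 at 0.10. The genes with the next smallest p were Bbc3 at 1.15 ± 0.13, which missed the threshold at an adjusted p of 0.050, Gpr65 at 0.63 ± 0.08 (0.081), and Notch1 at -0.89 ± 0.13 (0.13). Hspa1a and Hspa1b stood at -2.60 ± 0.42 and -2.45 ± 0.39 (both 0.17). Firre, Hspa1a and Hspa1b were higher in the tumour-free control antibody group than in each other group, as given above. Zpld2, Prkg1 and Cd59a were at least 3.43-fold, 3.80-fold and 1.90-fold higher and Cdkl4 and Col19a1 at least 5.02-fold and 2.70-fold lower, none past the threshold. Lists moved in 10 cases of 40 by camera, 9 up, in 0 with an estimated correlation (smallest adjusted p = 0.87) and in 0 by fry (smallest adjusted p = 0.21). Interferon response genes had a change above 0 in 45 of 46 and a median of 0.31, and none passed over all genes (18 adjusted over the list alone). Xaf1 stood at 0.53 ± 0.11, Oasl1 at 0.81 ± 0.17 and Rtp4 at 0.74 ± 0.17 (camera's adjusted p = 7.2e-18). Erythroid genes had a median of 0.82 (8 higher adjusted over the list alone; camera's adjusted p = 1.1e-06), endothelial genes 0.64 (6; 1.9e-05) and immediate early genes -0.28 (5 lower and 2 higher; 0.00016). These 4 lists had an adjusted p = 0.87 with an estimated correlation, and the immediate early list lost its call without replicate 5. The other lists that moved up were the Tfh (median 0.11, 2 adjusted over the list alone; camera's adjusted p = 0.011), regulatory T cell (0.14, 0; 0.019), cytotoxic (0.17, 0; 0.019), apoptosis (0.11, 1; 0.019), macrophage (0.24, 0; 0.023) and oxidative phosphorylation lists (0.13, 0; 5.2e-05). These 6 also had an adjusted p = 0.87 with an estimated correlation. The Tfh list lost its call without replicate 5, the oxidative phosphorylation list without 2, the regulatory list without 1 or 5, the apoptosis list without 2 or 5, and the cytotoxic and macrophage lists without 1 or 6. With 1 array left out the erythroid median lay between 0.52 without replicate 1 and 1.15 without 2. The endothelial one lay between 0.34 and 0.85, the interferon one between 0.20 and 0.38 and the immediate early one between -0.47 and -0.05. The counts of genes were 0, 2, 8, 8, 22 and 30 without replicate 1, 2, 3, 4, 5 and 6, and Olfr913 and Firre lost their calls without replicate 1 or 2. Other settings gave between 1 gene, with probes bright on all 8 arrays, and 21 genes, with normexp background correction.

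Under anti-IL-6R, 66 genes differed between tumour-bearing and tumour-free mice, 57 higher and 9 lower. Immunoglobulin segments made up 35 of the 57, a count that was 4 without replicate 7, 5 without 8 and 81 without 6. Chemokine genes of myeloid cells were among the others: Ccl8 at 2.84 ± 0.28, Ccl2 at 2.19 ± 0.32, Ccl9 at 1.15 ± 0.15, and Ccl7 at least 2.48-fold higher (adjusted p = 0.013, 0.044, 0.029 and 0.013). The macrophage genes Cd209b and Folr2 rose by 1.68 ± 0.18 and 1.65 ± 0.25, Stfa3 by 2.20 ± 0.20 and Tppp3 by 1.59 ± 0.20. Ak4 was higher too (adjusted p = 0.016), with a probe dim on both tumour-free arrays and so no exact size. Ccl2, Folr2 and Il10, given below, were each dim on 1 of these arrays, so their sizes are not exact either. Of the Tfh list, Ascl2 rose by 1.80 ± 0.18 and Cebpa by 0.96 ± 0.13, while Il21 (1.76 ± 0.30, adjusted p = 0.069), Pdcd1 (0.64 ± 0.12, 0.11) and Il4 (0.56 ± 0.17, 0.54) did not pass. Maf stood at 0.13 ± 0.09, Gzmb at 1.37 ± 0.24 (adjusted p = 0.072), Il10 at 2.15 ± 0.42 (0.12), Ifng at 0.36 and Tbx21 at -0.24. Prkg1 was lower (adjusted p = 0.028), with a probe dim on both tumour-bearing arrays and so no exact size. Olfr913, Zpld2, Gpr153 and Dcbld2 were at least 6.93-fold, 3.72-fold, 2.92-fold and 2.34-fold lower. By camera 17 lists moved, 11 up and 6 down, against 0 with an estimated correlation (smallest adjusted p = 0.17) and 0 by fry (smallest adjusted p = 0.064). The Tfh list had a median of 0.09 (6 higher adjusted over the list alone; camera's adjusted p = 1.8e-05, adjusted p = 0.57 with an estimated correlation). The c-Maf list had 0.34 (6 higher and 1 lower; 1.4e-06, adjusted p = 0.22 with an estimated correlation). The regulatory T cell list had a median of 0.16, with Tnfrsf9 at 0.63 ± 0.09 and Tnfrsf4 at 0.49 ± 0.07 past the threshold (5 adjusted over the list alone; camera's adjusted p = 6.8e-08, adjusted p = 0.22 with an estimated correlation). Inhibitory receptor genes had a median of 0.29 with 0 of 18 past the threshold (4 adjusted over the list alone; 6e-07, adjusted p = 0.17 with an estimated correlation). Cell cycle genes had a median of -0.24 with 0 of 54 past it (0 adjusted over the list alone; 3e-08, adjusted p = 0.70 with an estimated correlation), a call lost without replicate 5. Oxidative phosphorylation genes had a median of -0.18 with 0 of 41 above 0 (2.9e-10, adjusted p = 0.70 with an estimated correlation) and pan T cell markers -0.16 with 0 of 17 above 0 (0.00083, adjusted p = 0.75 with an estimated correlation). Cholesterol synthesis genes had a median of -0.24 (10 lower adjusted over the list alone; 8.1e-07, adjusted p = 0.57 with an estimated correlation). The ribosome list had -0.13 (5.5e-07, adjusted p = 0.75 with an estimated correlation) and the naive list -0.09 (0.038, adjusted p = 0.81 with an estimated correlation). The pan T cell, ribosome and naive lists lost their calls under quantile normalization, the pan T cell list also without replicate 8 and the naive list without 5, 7 or 8. Immediate early genes had a median of 0.25 (8.9e-07, adjusted p = 0.57 with an estimated correlation), Th2 genes 0.24 (0.0023, adjusted p = 0.26 with an estimated correlation), T cell activation genes 0.11 (0.00012, adjusted p = 0.26 with an estimated correlation) and NF-kappaB genes 0.07 (0.018, adjusted p = 0.57 with an estimated correlation). The last of these lost its call without replicate 5 or 8. Basophil and mast cell genes had a median of 0.36 (2 adjusted over the list alone; 9.5e-06, adjusted p = 0.22 with an estimated correlation), plasma cell genes 0.26 (3; 8.8e-05, adjusted p = 0.37 with an estimated correlation) and erythroid genes 0.05 (0; 0.39). The macrophage list's median, -0.01, and its test, upward (0.016), differed in sign (adjusted p = 0.77 with an estimated correlation), and its call depended on single arrays. The count of genes was 27, 28, 29, 31, 182, 10 and 14 without replicate 1, 2, 3, 4, 6, 7 and 8, and each of the 20 named genes lost its call without replicate 7, which left 1 array in the tumour-bearing group. It was 43 with quantile normalization, 29 without a trend, 19 with no filter and 7 in a fit of the 4 arrays alone.

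The difference between the antibody effects in the 2 hosts passed the threshold for 9 genes, 2 higher and 7 lower in tumour-bearing than in tumour-free mice, with 5409 at an unadjusted p under 0.05. This balance was not stable: with replicate 1, 3 or 7 left out, more genes were higher than lower. Neutrophil granule genes were among those lower, with Ltf at -5.23 ± 0.48 and Camp at -4.42 ± 0.33 (adjusted p = 0.027 and 0.017). Ngp and Mpo were lower too (adjusted p = 0.02 and 0.046), without an exact size, since their probes were dim on both arrays of 1 anti-IL-6R group. Tox2 stood at -1.51 ± 0.15 (0.041), with 0.13 at another probe, and Apol11b at -4.51 ± 0.49 (0.046). Firre at 3.90 ± 0.40 (0.041) and the pro-apoptotic gene Bmf at 1.29 ± 0.15 (0.048) were higher, with 0.18 and 0.21 at other probes. For Firre, only the tumour-free control antibody group stood apart, as given above. Maf at -0.99 ± 0.13 and Il4 at -1.94 ± 0.25 did not pass (both adjusted p = 0.057), nor did Pdcd1 at -1.16 ± 0.17 (0.063). Il21 stood at -1.41 ± 0.42 (0.11), Tbx21 at -0.70 ± 0.18 (0.095) and Ifng at 1.05 ± 0.36 (0.13). So for Maf, Il4, Pdcd1 and Il21 the antibody effect was not shown to differ between hosts. Gene lists differed in 22 of 40 cases by camera, 7 up and 15 down, in 0 with an estimated correlation (smallest adjusted p = 0.46) and in 7 by fry. The Tfh list had a median of -0.75 with 1 of 18 past the threshold (16 adjusted over the list alone; camera's adjusted p = 9.5e-10) and the cell cycle list -0.77 with 0 of 54 (49; 2.6e-19). Immediate early genes had 0.72 with 0 of 21 (13 higher and 2 lower; 1.8e-08) and erythroid markers -1.62 with 0 of 22 (19 lower and 1 higher; 3.9e-07), all 4 at an adjusted p = 0.46 with an estimated correlation. The median over all genes was -0.09, and -0.13 with median scaling. Without replicate 8 the count was 3, and Tox2, Ltf, Ngp, Mpo, Apol11b, Bmf and Firre lost their calls. It was 63, 14, 62, 339 and 468 without replicate 1, 3, 4, 6 and 7 and 6 without 2, and 41 with median scaling, 19 of them higher. It was 26 with a robust prior, 16 without a trend, 5 with quantile normalization, 3 with the mean of probes, 1 with probes bright on all 8 arrays and 0 with no filter.

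Averaged over both antibodies, 165 genes differed between hosts, 161 higher and 4 lower in tumour-bearing mice. Immunoglobulin segments were 98 of the 161, and between 56 and 110 with 1 array left out. Il21 rose by 2.47 ± 0.32, Gzmb by 1.56 ± 0.18, Ctla4 by 0.78 ± 0.13 and Ascl2 by 2.36 ± 0.23 (adjusted p = 0.011, 0.006, 0.035 and 0.0039). The chemokine genes Ccl8, Ccl12 and Ccl1 rose by 3.07 ± 0.21, 3.57 ± 0.46 and 2.13 ± 0.31, and Ccl7 was at least 2.29-fold higher. Sostdc1 rose by 3.66 ± 0.46, while Angptl2, Vat1l and Tnfsf4, the ligand of OX40, were at least 2.03-fold, 1.21-fold and 1.01-fold higher. Ccl12 and Sostdc1 were dim on 1 of the 2 tumour-free arrays under each antibody, so their sizes are not exact. Ptprk and Snora74a fell by 0.88 ± 0.15 and 0.59 ± 0.10 (adjusted p = 0.047 and 0.035). Pdcd1 at 1.22 ± 0.22 (0.058), Il4 at 1.53 ± 0.36 (0.18) and Maf at 0.63 ± 0.18 (0.38) did not pass. Ascl2, Ccl7, Ccl8 and Gzmb kept their calls with each array left out. The others lost theirs, Il21 without replicate 1 or 3, Sostdc1 without 4, Ccl12 without 3, 4 or 7, and Ccl1, Ctla4, Angptl2, Vat1l, Tnfsf4, Ptprk and Snora74a each without 5 or more of the 8 arrays in turn. The count was 87, 98, 96 and 81 without replicate 1, 2, 3 and 4. Averaged over both hosts, where antibody cannot be told apart from slide column, 2 genes were higher with anti-IL-6R. Bbc3 rose by 1.2 ± 0.09 and Gpr65, a proton-sensing receptor gene, by 0.67 ± 0.06 (adjusted p = 0.015 and 0.033), and 1924 genes had an unadjusted p under 0.05. Tsc22d3 at 0.66 ± 0.07 (0.069), Pik3ip1 at 0.57 ± 0.06 (0.082), Thbd at 1.12 ± 0.13 (0.082) and Dusp2 at 0.53 ± 0.06 (0.082) followed, and the lower genes nearest the threshold were Cdkl4, at least 3.29-fold lower (0.16), and Cd163l1 at -1.14 ± 0.20 (0.19). That count fell to 0 without replicate 1, 2, 6, 7 or 8 and to 1 without 3 or 4, and was 11 without 5. It was 4 with quantile normalization, 1 with median scaling, 0 without a trend and 12 with array weights.

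Across genes, which are not independent replicates, the antibody effect in tumour-bearing mice ran opposite to the tumour effect under control antibody (r = -0.734, covariance -0.176). Both differences use the same control antibody arrays of tumour-bearing mice, and unchanged groups simulated with the same spread gave r = -0.50 and a covariance of -0.0237. When simulated genes moved together as the residuals did, r ranged from -0.967 to 0.571, which includes the observed value. Of the genes called in both, 632 of 633 had opposite directions. Of these, 446 were higher with tumour and lower with antibody, against 35.0 for independent lists, and 186 the other way against 8.67. The lists are not independent, since the shared arrays enter the 2 differences with opposite sign, which by itself favours opposite calls. These counts therefore cannot show a reversal by the antibody. The 2 shared arrays cannot be split between the differences, so the excess over the simulated value is not free of them. The tumour effects under the 2 antibodies, which share no array, had r = -0.016 and a covariance of -0.0028 (simulated r -0.027 to 0.028, or -0.837 to 0.849 with genes moving together). By rank the correlation was -0.235. Of the genes called under control antibody, 519 of the 917 higher and 120 of the 425 lower had the same sign under anti-IL-6R. Leaving out 1 array gave an r between -0.135 without replicate 7 and 0.132 without replicate 8. Of the 66 genes called under anti-IL-6R, 49 were also called under control antibody, all 49 higher in tumour-bearing mice. Of these, 35 were immunoglobulin features, which are not independent of each other, and 14 were other genes, against 0.815 for independent lists of those. The 14 need not be independent of each other either. Some of them have no official-style symbol, so unlisted immunoglobulin features among them cannot be excluded. The antibody effects in the 2 hosts had r = -0.089 and a covariance of -0.0147 (simulated r -0.028 to 0.029, or -0.811 to 0.853 with genes moving together), with r between -0.224 without replicate 6 and 0.0738 without replicate 5.

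**Figure D3:**
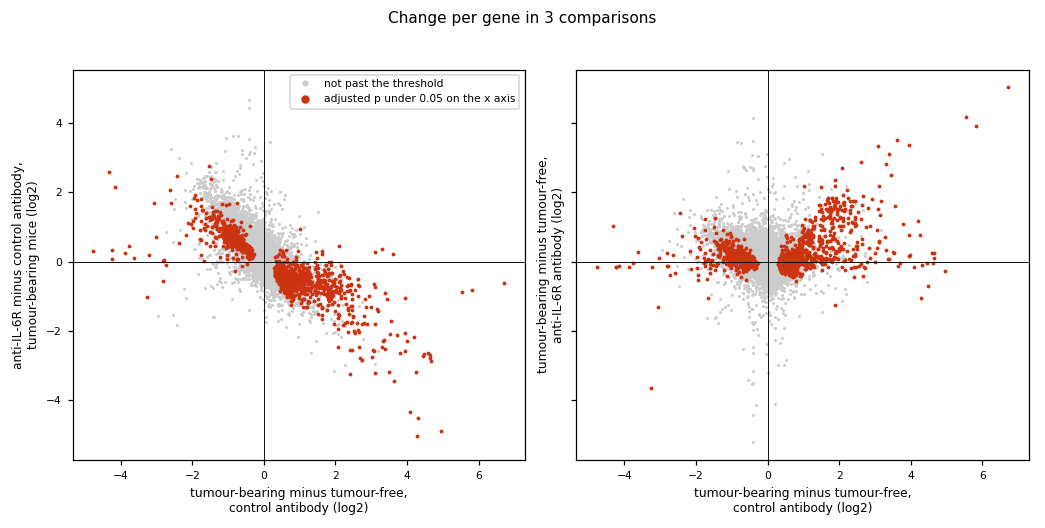
Log2 change of each gene between tumour-bearing and tumour-free mice under control antibody (x axes) against the change with anti-IL-6R in tumour-bearing mice (left) and the change between hosts under anti-IL-6R (right), with 21519 genes as points and the 1342 past the threshold on the x axis in red. Points fell along a descending diagonal on the left (r = -0.734), where both axes share 2 arrays, while on the right r was -0.016, with a correlation by rank of -0.235.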

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

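The tests of scaling, cell shares, precursor RNA and slide position below were chosen after the result was seen, while the counts over other splits of the arrays were planned before it. Each of the 31 results in this paragraph and the next was listed because a test of the difference between the antibody effects in tumour-bearing and tumour-free mice passed its threshold. For genes, the log2 difference was -5.34 for Ngp (adjusted p = 0.02), -5.23 for Ltf (0.027), -4.80 for 4930523O13Rik (0.048), -4.51 for Apol11b (0.046), -4.42 for Camp (0.017), -2.56 for Mpo (0.046), -1.51 for Tox2 (0.041), 1.29 for Bmf (0.048) and 3.90 for Firre (0.041). Ngp, Mpo and 4930523O13Rik were dim on both arrays of at least 1 group, so the sizes of their differences are not exact. Nor are those of Ltf and Apol11b, dim on 1 of the 2 tumour-free control antibody arrays. Other probes of Tox2, Bmf and Firre gave far smaller differences, as stated above.

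For gene lists, the median differences (camera's adjusted p) were -0.36 for Th2 (0.034), -0.52 for Th17 (0.027), -0.75 for Tfh (9.5e-10), -0.36 for regulatory T cell (0.00097), -0.35 for c-Maf (0.0037), -0.26 for interferon response (0.013), -0.77 for cell cycle (2.6e-19), -0.36 for chemokine receptor (0.0061), -0.27 for glycolysis (0.015), -0.39 for oxidative phosphorylation (4.5e-11), -0.39 for cholesterol synthesis (0.00049), -0.50 for plasma cell (0.03), -1.74 for neutrophil (2.4e-06), -1.62 for erythroid (3.9e-07) and -0.33 for pan T cell genes (0.0014). They were 0.13 for NF-kappaB (0.0078), 0.72 for immediate early (1.8e-08), 0.17 for heat shock (0.0053), 0.70 for B cell (2.5e-08), 0.46 for natural killer cell (0.0019), 0.36 for megakaryocyte (0.04) and 0.31 for endothelial genes (0.027). None held with an estimated correlation (smallest adjusted p = 0.46), and no interaction of a list mean passed (smallest adjusted p = 0.070). Of the 22 lists, 13 kept camera's call with each array left out in turn. The megakaryocyte list lost it in 5 cases and the plasma cell and endothelial lists in 4. By fry 7 of the 40 lists passed.

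Under control antibody, erythroid and neutrophil granule genes were higher on the arrays of tumour-bearing than of tumour-free mice. The erythroid score was 1.13 on replicate 3 and 0.13 on replicate 4, against 0.15 on replicate 7 under anti-IL-6R. Scaling between arrays did not account for it, since the lowest median shift of either list over 4 scalings was 0.88. A lower share of T cells alone would lower pan T cell markers and raise B cell markers along with erythroid ones. Instead the pan T cell median was 0.15 and the B cell median -0.70, beside an erythroid median of 1.60. The B cell and erythroid medians differed by 2.30, with a standard error of 0.29 over genes, not arrays. Genes of a list are not independent. The B cell value alone cannot decide this, since RNA of other cells could lower T and B cell markers alike. RNA of erythroid and neutrophil precursors in the isolates would raise most genes of both lists, and 88.9% (40 of 45) were higher, a value seen before the test was written, so this explanation may hold but is not shown. Whether such cells were more frequent because of the tumour was not tested.

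The Tfh list and Maf, Il21, Il4 and Pdcd1 were higher in tumour-bearing mice under control antibody and lower with anti-IL-6R. Scaling did not account for it (smallest median shift 0.47 over 4 scalings and both comparisons). A higher share of T cells would raise pan T cell markers as much as the Tfh list. Under control antibody their median was 0.15 against 0.86 for Tfh, so it did not account for that rise. The difference was 0.71, with a standard error of 0.24 over genes, which are not independent, and not over arrays. For the fall with anti-IL-6R, T cell share was not tested. There the pan T cell median was -0.24 against -0.60 for Tfh, so a part of the fall could follow T cell share. Slide row and column effects that add on the log2 scale would leave no interaction, and the list mean had one of -0.81 ± 0.14 (4 degrees of freedom), with an adjusted p of 0.070 over the 40 lists, and those of the 4 genes did not pass either. Slide position therefore stays open, since each position held 1 array, and so does an untested effect of tumour and IL-6 signalling.

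The cell cycle list was lower with anti-IL-6R in tumour-bearing mice. Scaling did not account for it (smallest median shift 0.63). Additive slide position stays open, since the interaction of the list mean, -0.73 ± 0.18, had an adjusted p of 0.073 over the 40 lists. Dividing erythroid precursors would tie the list to the erythroid score within groups, where the slope was 0.058 (95% interval -0.51 to 0.63, 3 degrees of freedom) against 1.21 between the groups. Fewer dividing T cells could also lower the list, and this was not tested. Nor was the list set against neutrophil or plasma cell scores, whose markers had medians of -1.55 and -0.43 in this comparison.

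For the host average, 1 of 34 splits of the arrays into 4 and 4 called as many as the 165 genes of the real split, which was that split itself, and the highest other count was 0. The other splits mixed the hosts, so host differences widened their residual spread and made calls unlikely. The low counts therefore say little about chance. Slide rows, which coincide with host, would single out the same split. For the antibody average 2 of 34 called as many as the real 2 genes, with 6 in another split, so chance could give that count.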

How the results depend on the processing

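The tests without immunoglobulin features and other cell types' markers were chosen after the result was seen, the others before. Where nothing else is said, the cause was not tested. Counts of genes changed, named by comparison with the main count first: hosts under control antibody, 1342 (no filter 569, no trend 621, array weights 764, adjusted p under 0.10 2695, 2-fold minimum 517; leaving out 1 array, 287 to 1245). Antibodies in tumour-bearing mice, 1261 (no filter 25, no trend 87, only the 4 arrays 697, 0.10 4108, 2-fold 321; 19 to 1715). Antibodies in tumour-free mice, 4 (normexp 21, quantile 9, no filter 8, all 8 arrays bright 1, mean of probes 2, no trend 11, robust prior 18, only the 4 arrays 18, 0.10 19; 0 to 30), with a higher share of 50%, against 81.0% with normexp, 66.7% with quantile and 66.7% with median scaling. Hosts under anti-IL-6R, 66 (quantile 43, no filter 19, no trend 29, only the 4 arrays 7, added setting 14, 0.10 131; 10 to 182). Difference of antibody effects, 9 (quantile 5, median scaling 41, no filter 0, all 8 arrays bright 1, mean of probes 3, no trend 16, robust prior 26, added setting 0, 0.10 1449; 3 to 468), with a higher share of 22.2%, against 0% with quantile and 46.3% with median scaling. Host average, 165 (added setting 27; 81 to 186). Antibody average, 2 (quantile 4, median scaling 1, no trend 0, array weights 12, 0.10 8, 2-fold 1; 0 to 11). The added setting gave 1075 and 1241 in the first 2 comparisons. It tests fewer genes, and a looser threshold or a 2-fold minimum changes counts by construction.

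Lists moved, with an estimated correlation, by fry and leaving out 1 array: 25, 0, 15 and 20 to 25 for hosts under control antibody; 26, 0, 13 and 22 to 25 for antibodies in tumour-bearing mice; 10, 0, 0 and 9 to 12 for antibodies in tumour-free mice (normexp 6, mean of probes 6). They were 17, 0, 0 and 15 to 20 for hosts under anti-IL-6R and 22, 0, 7 and 15 to 23 for the difference. Correlations were -0.016 for the tumour effects (all 8 arrays bright -0.108; -0.135 to 0.132), -0.089 for the antibody effects (no filter 0.0643, all 8 arrays bright -0.206; -0.224 to 0.0738) and -0.734 for the opposition of the antibody effect in tumour-bearing mice to the tumour effect (no filter -0.623, all 8 arrays bright -0.799; -0.790 to -0.663). Direction turned for Siglech between hosts under control antibody with the mean of probes (0.91), Lingo2 with anti-IL-6R in tumour-bearing mice with no filter (-0.36), the cell cycle and neutrophil lists with anti-IL-6R in tumour-free mice without replicate 5 (-0.12, up to 0.19 without others) and 6 (-0.078, up to 0.87), and, between hosts under anti-IL-6R, the naive list with quantile normalization (0.014), the neutrophil list without replicate 6 (0.22, down to -0.72 without others) and the interferon list without replicate 5 (-0.16). For named genes, 9132 values under planned settings kept their side of the threshold, 469 lost and 126 gained a call and 2 reversed, and leaving out 1 array gave 6451, 719, 150 and no reversal. Over all settings, 123 values past the threshold in neither changed sign and are counted as kept. An array left alone in its group is assumed to vary like the other groups. No paired analysis was possible because the groups share no replicate numbers. A slide block was not run, as there was 1 slide. Signal over background limits dim genes: levels under 24.2 to 36.3 cannot be told from 0.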

Other observations

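All tests in this part were chosen after the result was seen. Immunoglobulin heavy chain constant genes, which plasma cells and switched B cells express, were higher in tumour-bearing than in tumour-free mice under control antibody: gamma 1 at least 82.8-fold, gamma 2C by 5.81 ± 0.18, gamma 2B by 5.54 ± 0.15, gamma 3 by 3.79 ± 0.58 and epsilon at least 6.02-fold (n = 2 arrays per group; adjusted p = 4.0e-05, 6.0e-06, 3.9e-06, 0.011 and 0.0011). Kappa and lambda 1 rose by 1.12 ± 0.15 and 1.03 ± 0.18, while delta, which naive B cells express, fell by 0.88 ± 0.15 (adjusted p = 0.0076, 0.02 and 0.016). Mu stood at 0.43 ± 0.15 and alpha at 0.91 ± 0.41, neither past the threshold. A second delta feature and lambda constant 3 did not pass either (limma's adjusted p = 0.11 and 0.71), nor did a second mu feature. Of 181 immunoglobulin features 127 rose and 1 fell, with a median of 1.5. With 1 array left out between 62 and 133 rose. Gamma 3 lost its call without replicate 3, lambda 1 without 1, 2 or 3 and delta without 2 or 4.

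Under anti-IL-6R the median was 1.14 and 35 features were higher, among them gamma 1 at 5.04, gamma 2B at 4.18, gamma 2C at 3.92 and epsilon at least 3.13-fold, while gamma 3 stood at 1.08 and did not pass. The count fell to 4 without replicate 7 and 5 without 8, and epsilon lost its call without either, while gamma 1, 2B and 2C kept theirs with each array left out. Within tumour-bearing mice 34 features were lower and 2 higher with anti-IL-6R (median -0.57), including gamma 2B at -0.88 ± 0.15, gamma 2C at -0.81 ± 0.18 and gamma 3 at -2.64 ± 0.58 (adjusted p = 0.025, 0.041 and 0.042). These calls depended on single arrays: 0 features were lower without replicate 3, 3 without 4 and 1 without 8. Gamma 2B lost its call without replicate 3 or 4, gamma 2C without 1, 2, 3, 4, 7 or 8 and gamma 3 without 3, 4 or 8. In tumour-free mice 0 features were called by limma, with a median of -0.21.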
